A study of Mus musculus with 12 samples.

How the data were processed

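Polyadenylated RNA was sequenced from 12 libraries of sorted spleen CD4 T cells, 6 of LAG-3+ CXCR5+ PD-1lo/int cells (TLCP) and 6 of CXCR5+ PD-1hi Tfh cells, from C57BL/6 mice at day 21 of Leishmania donovani infection. Per the labels' protocols, CD4 T cells were enriched with magnetic beads and then sorted by flow cytometry, RNA was extracted with TRIzol and spin columns, and libraries were made with a poly(A) selection and a KAPA RNA HyperPrep kit. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.7.1a, the GRCm38 assembly and DESeq2 1.30.1 were used. The annotation release is not given in the sources used here.

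The deposited count files of the authors hold raw read counts per gene in the column layout of STAR gene counts, 1 file per library, for 55401 genes. The column of reads on the strand of the gene was used. Reads on the opposite strand came to 2.83% to 4.19% of the counts on both strands together, so genes that overlap on opposite strands were counted apart. Between 44.9% and 56.4% of all reads in the files were in the 4 classes that name no gene (unmapped, multimapping, no feature, ambiguous), and these stayed out of library sizes and tests. Multimapping reads came to 16.1% to 24.3%, so genes with near-identical copies, such as immunoglobulin segments and MHC genes, are less certain. CT010467.1, a gene with ribosomal RNA-like sequence, held 12.9% to 30.9% of the assigned counts. Its mean share was 17.3% in TLCP and 24.7% in Tfh.

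The authors' deposited result table holds log2 fold changes and p-values of their DESeq2 comparison, and a normalized signal per library, which is the count divided by 1 size factor. Whole reads were recovered from this deposited signal for 100% of the values (tolerance 0.01 reads), and they equalled the stranded counts. The refit on those reads called 3983 genes. The authors also deposited TPM values, whose columns sum to 1e6 within rounding and therefore include CT010467.1.

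Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and TLCP was compared with Tfh by the quasi-likelihood test with robust dispersion (2-sided), adjusted by Benjamini and Hochberg with a threshold of 0.05. Log2 fold changes are TLCP minus Tfh, and SE is the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD over 6 libraries. Gene lists for 16 T cell programs and 8 groups of other cells were fixed, with the tests, the rule for named genes and most alternatives, before the data were examined. The genes of the sort (Lag3, Cxcr5, Pdcd1) stand in no other list. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over 24 lists. The text names the sort markers, the 5 genes with the highest and the 5 with the lowest fold change (adjusted p under 0.05, at least 10 CPM in the higher group, the same direction in all 6 pairs, no antigen receptor segments, pseudogenes or unnamed models), the 3 members of each T cell list with the smallest p (2 for oxidative phosphorylation, glycolysis, ribosomal and cholesterol genes) and the 2 most abundant members of each other list. This gave 69 genes, of which 1 is not reported here. Positions are from GENCODE M21 on GRCm38, in which 54821 of the 55401 genes had spans identical to those in the files.

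The libraries are numbered 1 to 6 in both populations and the series description gives 6 mice. Deviations from the group means correlated at 0.127 to 0.318 between libraries with the same number, so the numbers were taken to pair the samples. Of the 12 libraries, 9 correlated best with their own number, and pairs with other numbers reached up to 0.209. The pairing is therefore inferred and not settled. The test without the block was the main test, and the block was an alternative. Libraries of mice 1 to 3 and of mice 4 to 6 also deviated together, with a median correlation of 0.0946 between other numbers of the same set and -0.13 across sets. No label names a batch. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 6.66).

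Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, limma voom, no filter, a stricter filter, unstranded counts, the replicate block, leaving out immunoglobulin and B cell list genes, leaving out each library, limma on log2(TPM + 1), and for lists an estimated correlation, fry and the block with an estimated correlation. Chosen after seeing the data were the recovered reads, leaving out ribosomal RNA genes, scaling by library totals alone, upper quartile scaling, mice 1 to 3 only, mice 4 to 6 only, and leaving out the 2 TLCP libraries with the most immunoglobulin counts. The method was tested on simulated data with 200 genes changed per simulation and 11860 to 11877 genes tested. For the comparison of TLCP with Tfh it recovered 77.4% of genes changed 2-fold and 95.6% of genes changed 4-fold in 3 simulations, with 7 to 14 false calls in each. Genes in these simulations vary independently, which genes of the real lists do not.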

Results

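Messenger RNA was profiled in 2 CD4 T cell populations sorted from the spleens of C57BL/6 mice at day 21 of infection with Leishmania donovani, a protozoan parasite that causes visceral leishmaniasis. The first population, called TLCP here, carried LAG-3 and the follicle-homing receptor CXCR5 with low to intermediate PD-1. The second, called Tfh here, was CXCR5+ PD-1hi T follicular helper cells, which according to the series description were mostly germinal center Tfh cells. The series description gives 6 mice. Each population was represented by 6 libraries, numbered 1 to 6. Between 6939770 and 12688306 reads per library were assigned to genes, and 12015 genes had enough counts to be tested. A count of 0 in a library allows a level of up to 0.236 to 0.432 counts per 1e6 assigned reads (3 counts of the total), and these floors cover counting error only. Levels are given as CPM, TMM-scaled counts per 1e6 reads.

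The genes of the sort were examined first, as a check of the labels and not as a finding. The cell type label of TLCP names LAG-3, CXCR5, PD-1 and CD4. Tcf7, Icos and Cd3e were fixed in the same list, and their values are results rather than a check of that label. Lag3 mRNA was 189 ± 31.2 CPM (SD, n = 6) in TLCP and 40.5 ± 11.1 CPM (SD, n = 6) in Tfh. Pdcd1, which encodes PD-1, was 36.6 ± 4.60 CPM in TLCP and 318 ± 34.8 CPM in Tfh, a log2 fold change of -3.12 (SE 0.092, adjusted p = 7.7e-15). Cxcr5 was 277 ± 56.9 CPM in TLCP and 849 ± 78.2 CPM in Tfh, so both populations held the transcript and it was 3.07-fold lower in TLCP. Tcf7, which encodes TCF-1, fell from 1610 ± 126 CPM in Tfh to 694 ± 166 CPM in TLCP (log2 fold change -1.22, adjusted p = 2.9e-05). Cd4 was 725 ± 47.1 CPM in TLCP and 955 ± 47.5 CPM in Tfh (log2 fold change -0.40). Icos and Cd3e, which encode a costimulatory receptor and a chain of the T cell receptor complex, had log2 fold changes of -0.09 (adjusted p = 0.58) and -0.05 (adjusted p = 0.54) and did not pass the test. Scaled by library totals alone, these values were 0.08 for Icos and 0.12 for Cd3e. In GRCm38 coordinates Lag3 lies on chromosome 6 from 124904361 to 124911705, Pdcd1 on chromosome 1 from 94038305 to 94052553 and Cxcr5 on chromosome 9 from 44511787 to 44561877, each a protein-coding gene on the minus strand.

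**Figure D1:**
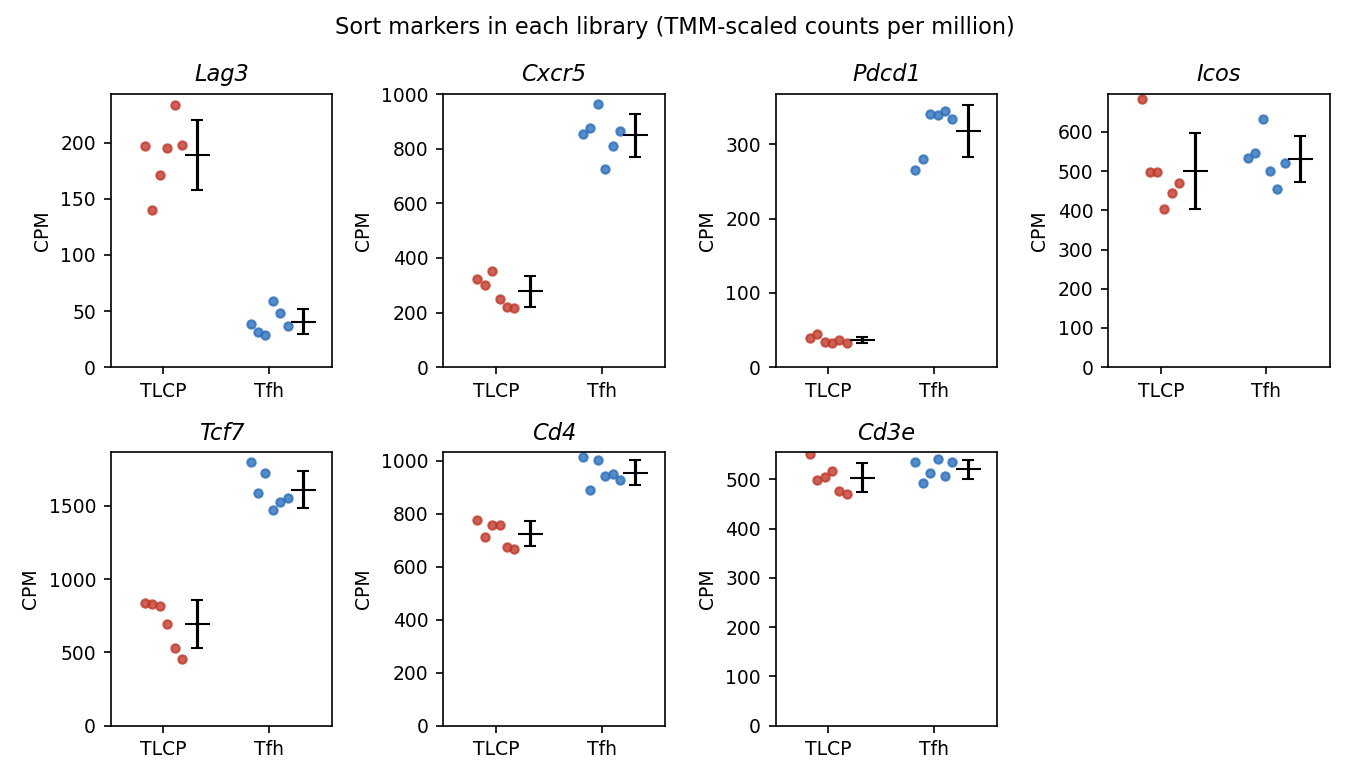
Genes of the list of sort markers in each library. Each panel plots TMM-scaled CPM of 1 gene on a linear axis from 0 for the 6 TLCP and the 6 Tfh libraries, with the mean and SD as black bars. Every TLCP library lies above every Tfh library for Lag3 and below every Tfh library for Pdcd1 and Cxcr5.

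The comparison of the 2 populations asked how far the transcriptome of TLCP differs from that of Tfh cells, which share surface markers with it. Of the 12015 genes tested, 3983 differed, 2014 higher and 1969 lower in TLCP. Of these, 1170 differed by at least 2-fold, 789 of them higher and 381 lower. In 3413 of the 3983 genes all 6 numbered pairs moved the same way. Immunoglobulin genes made up 103 of the 789 genes that were at least 2-fold higher. When libraries were scaled by their totals alone, the median log2 fold change of all tested genes was 0.17 in place of -0.004, and 3207 genes were higher and 893 lower. Limma on the deposited TPM values gave 3176 higher and 465 lower, with a median log2 fold change of 0.26. Of the 3983 genes, all were tested with the totals alone, where 19 changed sign, and 3854 on the TPM values, where 377 did. Of those that changed sign 0 were called in the new direction and 0 had a change of at least 2-fold.

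The highest fold changes, among named genes with at least 10 CPM in the higher group and the same direction in all 6 pairs, were those of Mcpt8, Il10, Miat, Clec2l and Prss34. Il10, which encodes an immunoregulatory cytokine, was 46.8 ± 13.3 CPM in TLCP and 1.63 ± 0.848 CPM in Tfh (n = 6 each), a log2 fold change of 4.85 (SE 0.28, adjusted p = 1.3e-08). It lies on chromosome 1 from 131019845 to 131024974. Mcpt8 and Prss34, proteases of basophils and mast cells, were 37.9-fold (log2 SE 0.57) and 21.1-fold (log2 SE 0.84) higher in TLCP, at 17.4 ± 9.91 and 14.4 ± 8.98 CPM. Miat, a long noncoding RNA, and Clec2l, a C-type lectin gene, were 25.3-fold and 21.6-fold higher. The lowest fold changes were those of Gal, Rgs8, Il4, Cpeb1 and Abcc3. Gal, which encodes the neuropeptide galanin, had 0 counts in all 6 TLCP libraries and 14.3 ± 5.20 CPM in Tfh. Against a floor of 3 counts over the TLCP group this is at least 280-fold lower. Il4, a cytokine that Tfh cells supply to B cells, was 0.583 ± 0.457 CPM in TLCP and 17.4 ± 5.63 CPM in Tfh, or 29.7-fold lower (adjusted p = 2.4e-07). Rgs8, a regulator of G protein signaling, was 38.7-fold lower. Cpeb1, an RNA-binding protein gene, was 23.6-fold lower and Abcc3, a transporter gene, 19.7-fold lower.

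**Figure D2:**
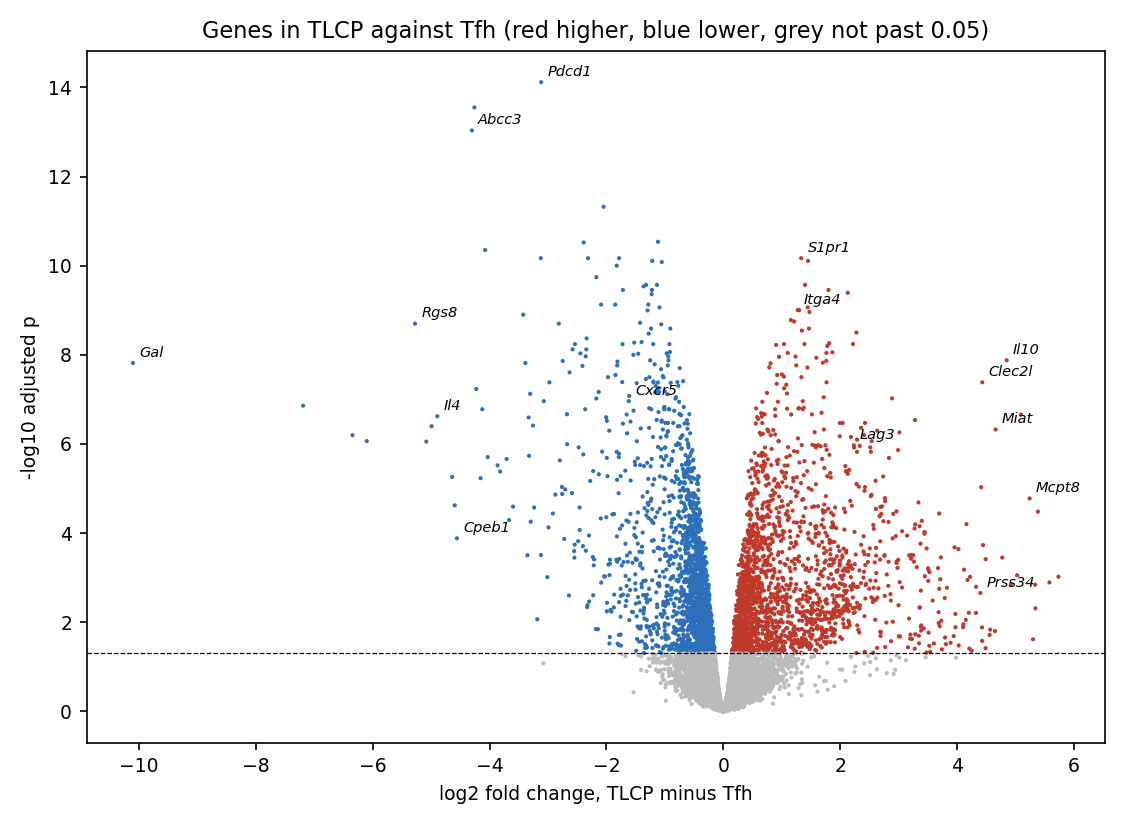
Genes in TLCP against Tfh. Each point is 1 of 12015 tested genes, placed by its log2 fold change (TLCP minus Tfh) and by -log10 of its adjusted p from edgeR, and the dashed line marks an adjusted p of 0.05. The 2014 genes in red were higher and the 1969 in blue lower in TLCP.

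Genes of the germinal center Tfh program were lower in TLCP. Of the 22 members of this list, all tested, 19 fell, 0 rose and 3 did not pass the test, and adjusted over the list alone 19 fell and 1 rose. The median log2 fold change was -1.26. S1pr2, a receptor that retains cells in germinal centers, fell from 55.0 ± 7.28 to 15.2 ± 2.67 CPM (log2 fold change -1.85, SE 0.12). Cd40lg, the ligand through which T cells activate B cells, had a log2 fold change of -1.28 (SE 0.092) and Tnfsf8, the CD30 ligand gene, one of -1.25 (SE 0.095). The camera test gave an adjusted p of 1.2e-25, and the adjusted p was 0.0011 with an estimated correlation. This was the 1 list of 24 that passed with an estimated correlation.

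Genes of progenitor and memory T cells moved both ways. Of 20 members, 10 rose, 7 fell and 3 did not pass, and adjusted over the list alone 12 rose and 7 fell. Most of the lower calls depended on the scaling, since 13 rose and 2 fell with the totals alone. Limma on the TPM values, which also changed the test and the genes tested, gave 13 higher and 1 lower. S1pr1, which directs exit from lymphoid tissue, rose from 102 ± 10.5 to 256 ± 15.9 CPM (log2 fold change 1.33, SE 0.072, adjusted p = 6.8e-11). Ccr7, a lymph node homing receptor, rose from 18.1 ± 4.57 to 51.7 ± 9.44 CPM. Id3, a transcriptional inhibitor, fell from 31.3 ± 2.29 to 9.46 ± 2.05 CPM (log2 fold change -1.72, SE 0.13). Tcf7, reported with the sort markers, also belongs to this program and was lower in TLCP. The camera test placed the list higher (adjusted p = 0.00099), but the adjusted p was 0.28 with an estimated correlation. S1pr1 and Ccr7 are also expressed by B cells, and B cell transcripts were higher in the same libraries, with Ighm 9.07-fold higher. Over the 6 TLCP libraries S1pr1 was 233 to 277 CPM and Ccr7 34.7 to 61.6 CPM. Ighm was 3730 to 22786 CPM there, and Cd74, an MHC class II pathway gene that B cells express, 316 to 1207 CPM. S1pr1 did not rise with either of these over the TLCP libraries.

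Th1 and cytotoxic genes were mostly higher in TLCP. Of 27 members, 22 rose, 1 fell and 4 did not pass, and adjusted over the list alone 23 rose and 2 fell. Runx3, a transcription factor of cytotoxic lymphocytes, rose from 18.1 ± 3.78 to 63.6 ± 9.75 CPM (log2 fold change 1.81, SE 0.13, adjusted p = 5.5e-09). Il2rb, an interleukin receptor chain, rose by a log2 fold change of 0.76 (SE 0.089). The member that fell was Stat4, a transcription factor downstream of interleukin-12 signaling, at -0.81 (SE 0.075, adjusted p = 9.0e-08). Camera gave an adjusted p of 4.2e-11, and it was 0.27 with an estimated correlation and 0.021 with an estimated correlation and the replicate block. Jchain, a plasma cell transcript, was 15.5-fold higher in the same libraries.

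Genes associated with type 1 regulatory T cells rose in 10 of 13 members, fell in 2 and did not pass in 1, with the same numbers adjusted over the list alone. Besides Il10, Irf4, a transcription factor induced by antigen receptor signaling and also high in plasma cells, rose by a log2 fold change of 1.04 (SE 0.078). Egr2, a transcription factor induced by the T cell receptor, fell from 62.8 ± 4.76 to 28.2 ± 4.85 CPM. For this list camera gave an adjusted p of 3.1e-08, and the adjusted p was 0.074 with an estimated correlation. Plasma cell transcripts were higher in the same libraries, with Jchain 15.5-fold higher. Among genes of regulatory and follicular regulatory T cells, 9 of 14 rose, 2 fell and 3 did not pass, and adjusted over the list alone 10 rose and 3 fell. Foxp3, the lineage factor of regulatory T cells, rose from 32.6 ± 7.78 to 84.4 ± 9.0 CPM (log2 fold change 1.38, SE 0.12). Il2ra, which encodes CD25, rose from 20.7 ± 7.04 to 111 ± 7.55 CPM (log2 fold change 2.43, SE 0.18) and Capg, an actin-capping protein gene, by 1.39 (SE 0.15). For the regulatory list camera gave an adjusted p of 4.4e-05, and it was 0.28 with an estimated correlation. The plasma cell transcripts were higher beside this list too, and the list was not tested against them. Over the TLCP libraries Jchain was 550 to 3012 CPM. Foxp3 was 73.9 to 95.9, Il2ra 104 to 123 and Capg 43.5 to 68.0 CPM there, and these 3 genes did not follow Jchain.

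Trafficking genes rose in 14 of 20 members, fell in 5 and did not pass in 1, with the same numbers adjusted over the list alone. Itga4, the integrin alpha 4 chain, rose from 605 ± 84.9 to 1463 ± 104 CPM (log2 fold change 1.27, SE 0.084). Camera gave an adjusted p of 7.8e-06 for trafficking genes, and the adjusted p was 0.074 with an estimated correlation. On the TPM values 14 rose and 2 fell. S1pr1 and Ccr7 belong to this list too, beside the higher B cell transcripts given with them, which S1pr1 did not follow over the TLCP libraries. In the list of inhibitory receptors and exhaustion genes 8 of 14 rose and 3 fell, with the same numbers adjusted over the list alone, and 7 of 12 rose and 1 fell on the TPM values. Entpd1, the ectonucleotidase CD39, was 5.76-fold higher and Ctla4 1.72-fold higher, whereas Cd160 fell from 23.5 ± 1.87 to 3.52 ± 1.45 CPM. This list did not pass (camera adjusted p = 0.13) and passed with the replicate number as a block (0.028), which is the pairing of libraries by mouse number. With an estimated correlation its adjusted p was 0.47, and 0.41 with the block as well. Cytokine and ligand genes split into 5 higher and 6 lower of 16, 5 higher and 7 lower adjusted over the list alone, and 8 higher and 4 lower of 19 on the TPM values. Their median log2 fold change was -0.19 (0.29 on the TPM values), their mean was 0.14, and camera pointed lower without passing (adjusted p = 0.14).

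Early response genes of the T cell receptor included 8 that rose and 2 that fell among 22, with the same numbers adjusted over the list alone. Nr4a3, an orphan nuclear receptor induced by antigen, fell from 30.8 ± 4.29 to 14.2 ± 2.41 CPM. The camera adjusted p of 0.024 became 0.62 with an estimated correlation, 0.058 without TLCP replicate 4 and 0.056 without Tfh replicate 2. Some members also differed between mice: Junb, named after its values were seen and not past the test between populations (adjusted p = 0.66), was 137 to 203 CPM in the 6 libraries of mice 1 to 3 and 251 to 323 CPM in the 6 of mice 4 to 6. With the replicate block 12 members rose and 2 fell, in mice 1 to 3 alone 11 rose and 3 fell, and in mice 4 to 6 alone 12 rose and 3 fell. Of 34 interferon-stimulated genes 14 rose and 3 fell, and adjusted over the list alone 15 rose and 4 fell. With the totals alone 17 rose and 1 fell, and on the TPM values 15 rose and 0 fell. Gbp7, a guanylate-binding protein gene, was 2.86-fold higher, Samhd1, a dNTP hydrolase gene, 1.85-fold higher and Stat2 1.49-fold higher. Interferon-stimulated genes had a camera adjusted p of 0.00091, and it was 0.31 with an estimated correlation and 0.021 with an estimated correlation and the replicate block. Ighm and Jchain were 9.07-fold and 15.5-fold higher in the same libraries as the early response and interferon-stimulated genes. Of 17 genes fixed for Th2 and Th17 cells, 10 had enough counts to be tested. They did not pass as a list (camera adjusted p = 0.89, 5 higher and 3 lower of 10, in both adjustments, and 6 higher and 1 lower with the totals alone and on the TPM values). Il1r1, an interleukin-1 receptor gene, was 9.88-fold lower, Gata3, the Th2 lineage factor, 1.36-fold lower, and Tmem176b, a membrane protein gene, 3.62-fold higher.

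Of 73 oxidative phosphorylation genes 32 fell and 0 rose, and adjusted over the list alone 37 fell. Ndufs6 and Uqcrh, subunits of respiratory complexes, had log2 fold changes of -0.65 (SE 0.083) and -0.47 (SE 0.071). Camera gave an adjusted p of 2.7e-05, it was 0.35 with an estimated correlation, and the median log2 fold change of -0.24 was -0.07 with 7 genes lower when libraries were scaled by their totals alone, and 0.06 with 1 gene lower on the TPM values. Mitochondrial ribosomal RNA held 4.30% to 5.87% of the counts in the TLCP libraries and 6.47% to 8.47% in the Tfh libraries. Ighm and Jchain were 9.07-fold and 15.5-fold higher in TLCP. Whether the fall follows from such differences in RNA composition was not tested. Glycolysis genes did not pass as a list (camera adjusted p = 0.25), and their median log2 fold change was -0.29, or 0.0055 on the TPM values. In it 2 genes rose and 7 fell of 17, and adjusted over the list alone 2 rose and 8 fell. With the totals alone 2 rose and 1 fell, and on the TPM values 3 rose and 0 fell. Slc2a3, a glucose transporter gene, was 1.79-fold higher, and Hk1, a hexokinase gene, 1.23-fold lower. Cell cycle genes (8 higher and 7 lower of 39 in both adjustments, camera adjusted p = 0.82) did not pass as a list. Their counts were 17 higher and 0 lower with the totals alone, 15 and 0 on the TPM values, 3 and 11 in mice 1 to 3 alone and 7 and 0 in mice 4 to 6 alone. Mki67, a proliferation marker, was 874 ± 164 CPM in TLCP and 668 ± 48.6 CPM in Tfh (adjusted p = 0.0074, and 0.34 in mice 1 to 3 alone). Tk1 was 1.51-fold higher and Ccnb1 1.45-fold lower. Ribosomal protein genes (10 higher and 7 lower of 78, 9 and 7 adjusted over the list alone, camera adjusted p = 0.40) and cholesterol synthesis genes (4 higher and 2 lower of 21, 4 and 1 adjusted over the list alone, camera adjusted p = 0.52) did not pass either. With the totals alone 29 ribosomal protein genes were higher and 0 lower, and on the TPM values 32 and 0 of 79. Mice 1 to 3 alone gave 20 and 0, and mice 4 to 6 alone 5 and 12. For cholesterol synthesis genes the totals alone gave 9 higher and 0 lower of 21, limma on the TPM values 9 and 0 of 20, and mice 4 to 6 alone 1 and 0. Among them Rps13 and Rpl10a were 1.47-fold and 1.65-fold higher, and Nsdhl 1.44-fold higher.

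**Figure D3:**
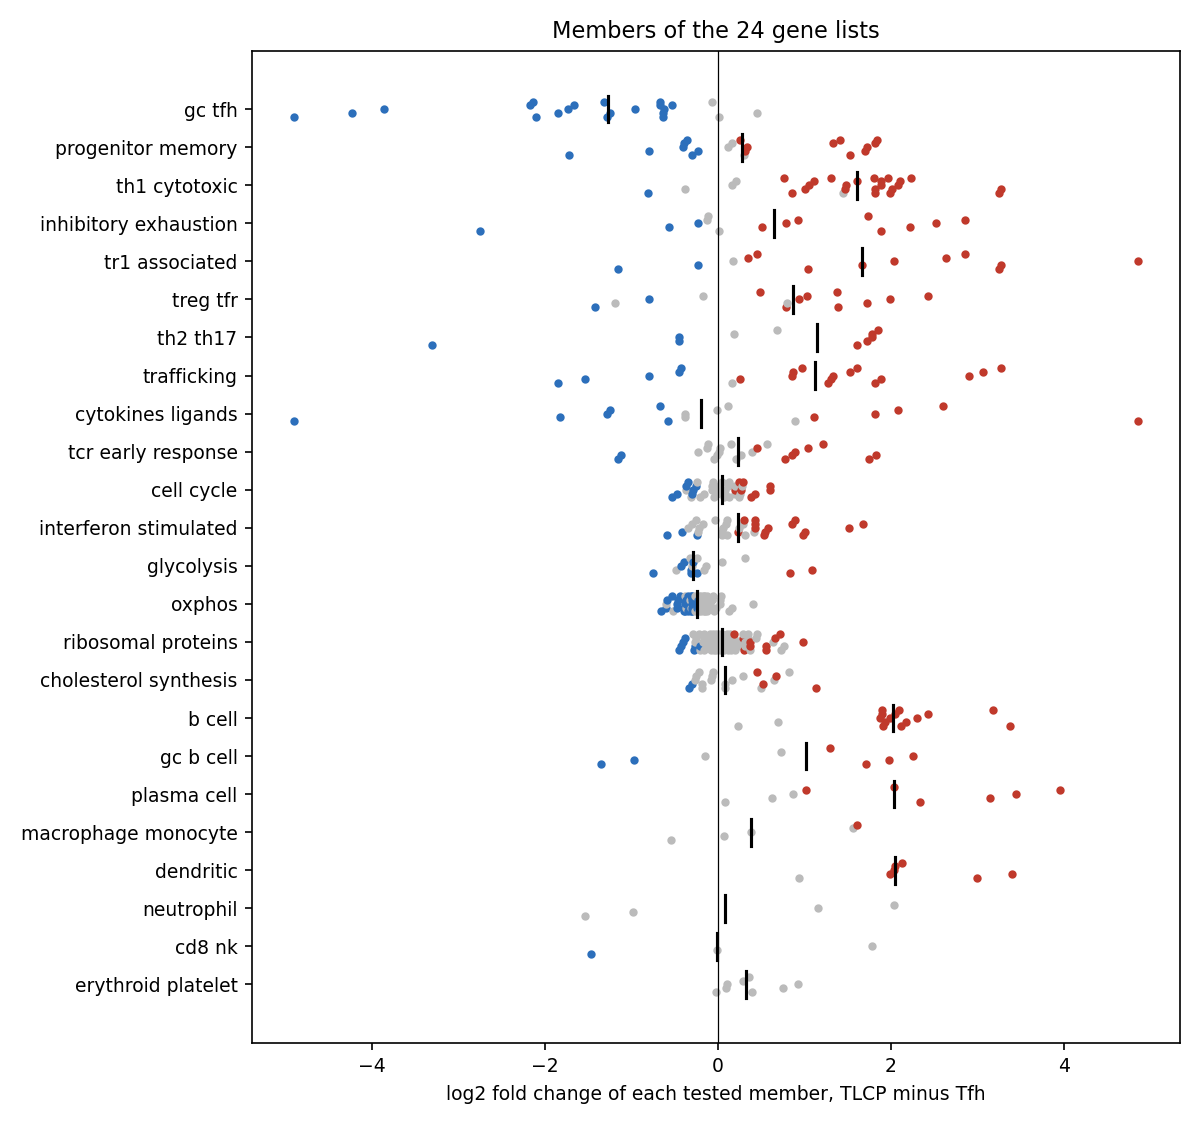
Members of the 24 gene lists. Each point is the log2 fold change (TLCP minus Tfh) of 1 tested member, red if higher, blue if lower and grey if not past an adjusted p of 0.05 over all genes, and the black bars are medians. The germinal center Tfh list has 19 members lower and 0 higher, and its median is -1.26.

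Transcripts of other cell types were measured with lists for 8 of them. Some lists had many members with too few counts to be tested. The main test covered 7 of 11 dendritic cell, 5 of 15 macrophage and monocyte and 4 of 10 neutrophil genes. It covered 3 of 8 CD8 T cell and NK cell genes and 8 of 15 erythroid and platelet genes. Of 16 B cell genes 14 rose and 0 fell, and adjusted over the list alone 15 rose. In mice 1 to 3 alone 6 rose and in mice 4 to 6 alone 3 rose, while the median log2 fold change of 2.022 was 2.063 and 2.003 there. Ighm, the immunoglobulin M heavy chain, was 10855 ± 7174 CPM in TLCP and 1197 ± 305 CPM in Tfh (log2 fold change 3.18, SE 0.45), and Igkc, the kappa light chain, was 10.4-fold higher. Immunoglobulin genes held 0.731% to 4.64% of the counts in the TLCP libraries and 0.11% to 0.384% in the Tfh libraries. Of 9 plasma cell genes 6 rose and 0 fell in both adjustments. Jchain was 1533 ± 883 CPM in TLCP and 99 ± 46.6 CPM in Tfh, whereas Ighg2c had a log2 fold change of 0.63 (SE 0.78, adjusted p = 0.58). Of 7 dendritic cell genes 6 rose and 0 fell in both adjustments, and 2 of 8 rose in mice 4 to 6 alone, while the median log2 fold change of 2.046 was 2.001 there. Cd74 and H2-Aa, genes of the MHC class II pathway that B cells also express, were 4.37-fold and 4.13-fold higher. The camera adjusted p values of the B cell, plasma cell and dendritic cell lists were 1.0e-06, 0.00068 and 0.00026, and they were 0.31, 0.35 and 0.28 with an estimated correlation. With an estimated correlation and the replicate block all 3 had an adjusted p of 0.021. Mcpt8 and Prss34, named above, are transcripts of basophils and mast cells, for which no list was fixed.

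The other 5 lists did not pass. Macrophage and monocyte genes had 1 of 5 higher, 2 adjusted over the list alone (camera adjusted p = 0.35, 0.036 with the replicate number as a block, and 0.35 with the block and an estimated correlation). On the TPM values 7 of 10 were higher, with a median log2 fold change of 1.10, and in mice 4 to 6 alone 4 of 11, with a median of 1.07. The list passed in mice 4 to 6 alone (adjusted p = 0.0077) and with no filter on low counts (0.00030). Mpeg1 was 3.06-fold higher and Lyz2 had a log2 fold change of 0.38 (SE 0.47). Germinal center B cell genes had 4 higher and 2 lower of 8 in both adjustments (camera adjusted p = 0.61), with Fas, which T cells also express, 1.96-fold lower and Neil1 at -0.15 (SE 0.14), or 0.03 scaled by library totals alone. Of the 3 CD8 T cell and NK cell genes 0 rose and 1 fell in edgeR, and 1 rose and 1 fell adjusted over the list alone, with DESeq2 and with the replicate block (camera adjusted p = 0.59). Limma voom, the totals alone and the TPM values called 0 higher and 1 lower. The gene that rose was Cd8a, named after its values were seen, with a log2 fold change of 1.78 (SE 0.74, adjusted p = 0.081 over all genes) and higher in all 6 pairs. Cd8b1 had a log2 fold change of -0.01 (SE 0.24), or 0.16 scaled by library totals alone, and Klrb1c fell from 11.6 ± 3.17 to 4.22 ± 1.06 CPM. Of 4 neutrophil genes and 8 erythroid and platelet genes 0 passed in edgeR, also adjusted over the list alone (camera adjusted p = 0.60 and 0.50). At an unadjusted p under 0.05 there were 2 neutrophil genes and 0 of the others, DESeq2 and limma voom called 0 in both lists, and limma on the TPM values called 1 in each. The replicate block called 1 erythroid gene, scaling by totals alone 1 neutrophil gene, and mice 1 to 3 alone 3 of 8 erythroid genes and 1 of 2 neutrophil genes, all higher. Mice 4 to 6 alone called 0 of 8 erythroid genes and 1 of 5 neutrophil genes, which was lower, and the neutrophil median was -1.13 there. The erythroid and platelet list passed in mice 1 to 3 alone (adjusted p = 0.025). S100a9 and Mpo had log2 fold changes of -1.53 (SE 1.2) and 2.03 (SE 0.91), and Hbb-bs and Car1 of 0.37 (SE 0.57) and 0.09 (SE 0.65).

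**Figure D4:**
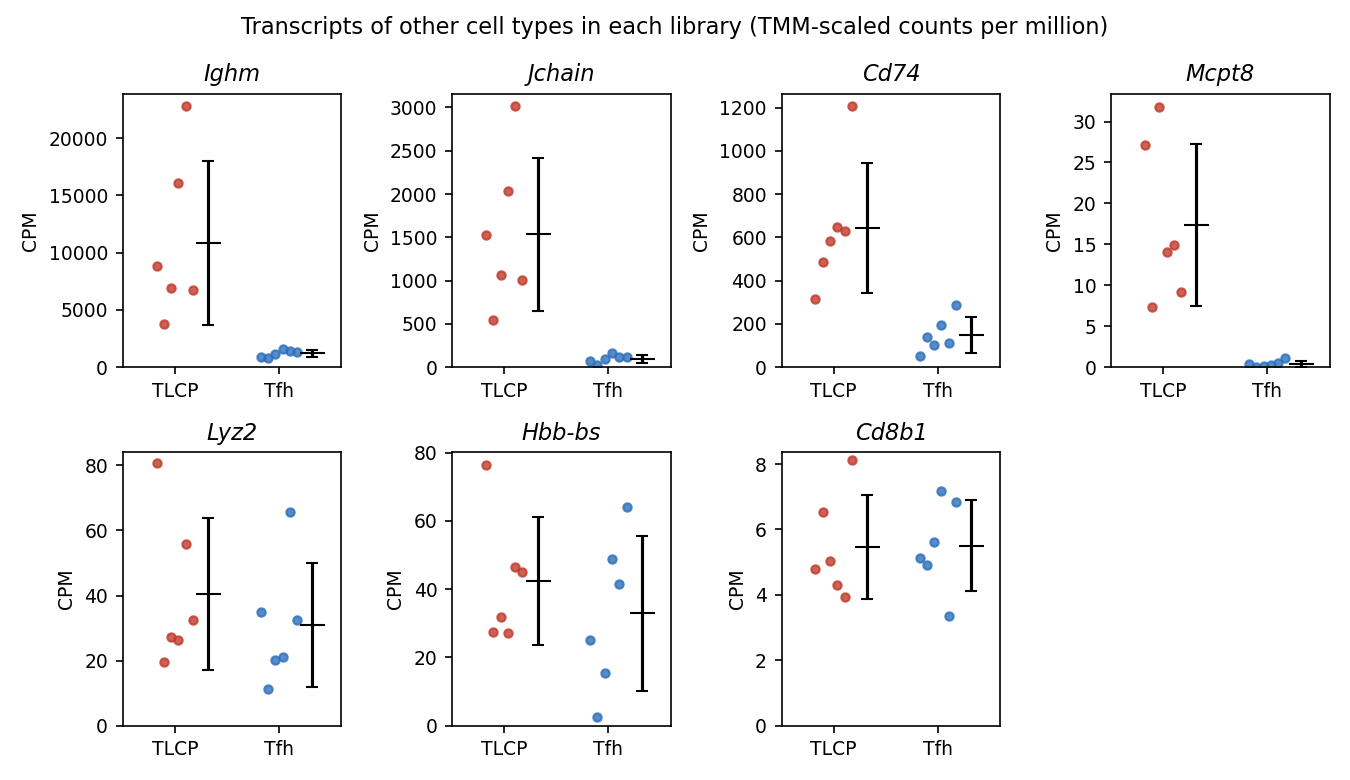
Transcripts of other cell types in each library. Each panel plots TMM-scaled CPM of 1 gene on a linear axis from 0 for the 6 TLCP and the 6 Tfh libraries, with the mean and SD as black bars. Ighm, Jchain, Cd74 and Mcpt8 are higher in the TLCP libraries, whereas the means of Lyz2, Hbb-bs and Cd8b1 differ by less than the SD.

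Of the 24 lists, 12 passed the camera test with a preset correlation of 0.01, 10 higher and 2 lower. In 52 regroupings of the same 12 libraries with 3 of each population on both sides, a median of 4 lists and up to 12 passed the same test. In the authors' deposited table there were 4411 genes that had an adjusted p under 0.05, 2418 higher and 1993 lower in TLCP. Of these, 3872 were also called in the refit with the same direction and 0 with the opposite direction.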

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

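The tests of scaling and of other cell type genes against the B cell list, some genes named there, and the test of CD8 T cells were chosen after the results were seen, and the ranks of single lists among other groupings, and the division of these by their share of each population, were added after the number of lists was seen. Among 175 sets of 6 libraries examined, 6 had a library far from the others by Dixon's gap to range ratio, where chance gives about 1 in 20. Tnfsf8 was 92.6 CPM in TLCP replicate 6 and 123 to 139 in the others (ratio 0.693). Ccnb1 was 18.2 CPM in Tfh replicate 6 and 21.2 to 22.7 in the others (0.689). Neil1 was 8.41 CPM in TLCP replicate 1 and 10.9 to 12.5 in the others (0.655). Nsdhl was 11.8 CPM in Tfh replicate 4 and 17.9 to 20 in the others (0.791), and Prss34 was 3.34 CPM there and 0 to 0.62 in the others (0.672). The share of opposite-strand reads was 3.71% in Tfh replicate 3 and 2.83% to 3.11% in the others (0.678).

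B cell and plasma cell transcripts were higher in TLCP. The 13 B cell genes that are not immunoglobulin genes rose and fell together over the 6 TLCP libraries, with a median pairwise correlation of 0.963. The 95th percentile of 1000 expression-matched lists, drawn from genes outside all lists and so not markers of 1 cell type, was 0.146. The correlation is what RNA of B cells in the sorted fraction would give, although the sort for CD4 T cells should remove B cells. Ighm, at 10855 CPM in TLCP, is not among the 13. It was highest in TLCP replicates 5 and 4, as was Jchain, whereas Cd74 was highest in TLCP replicate 6. The median log2 fold change of the 13 genes was 2.18 with the totals alone and 1.99 with TMM, which trims extreme genes. TMM thus kept 91.5% (jackknife SE 2.12) of it. A change of scaling moves all genes about alike, and the median of all genes moved only from 0.17 to -0.004. The choice between these 2 scalings is therefore too small to give the B cell difference. The percent kept follows from the size of that difference and is no separate test of a scaling skewed by abundant genes. The 20 tested genes of the CD8 T cell and NK cell, erythroid and platelet, macrophage and neutrophil lists were set against these 13 B cell genes. Of the 20, 12 lay below the B cell median (1.99) by more than 2 jackknife SE and 0 lay above it by as much. Among the 12 were Klrb1c at -1.46, Cd8b1 at -0.01, Hmox1 at -0.54 and Hbb-bs at 0.37. The 12 argue against a lower share of T cells that raised every other cell type alike. The other 8 genes, such as Cd8a at 1.78, Mpeg1 at 1.61 and Mpo at 2.03, were not set apart from the B cells, and in mice 1 to 3 alone the erythroid and platelet median was 1.72, so a rise of some other cell types with the B cells stays open, as does expression of these genes by TLCP themselves, which was not tested. Dendritic cell genes (median 2.05) and basophil and mast cell transcripts such as Mcpt8 at 5.24 were not among the 20 and rose about as much or more. The dendritic list includes MHC class II pathway genes that B cells also express, such as H2-Aa at 2.05. Its median therefore cannot be told apart from the B cell rise.

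Th1 and cytotoxic genes were higher in TLCP. The median log2 fold change of all 27 members was 1.62 above that of Cd8b1 (jackknife SE 0.309), but that of Cd8a, the other CD8 chain, named after its values were seen, was 1.78 and not below the list (difference -0.167, SE 1.03). CD8 T cells that carry both chains, which the CD4 enrichment and the sort should remove, would raise Cd8b1 along with the list. Cd8b1 did not rise (log2 fold change -0.01, SE 0.24). This argues against RNA of such cells as the source of the median rise of the list. The rise of Cd8a did not pass over all genes (SE 0.74), and RNA of cells with Cd8a alone was not tested and stays open. When the B cell and plasma cell levels were entered in a linear fit, a median of 1.83% of the group difference in CPM of the 22 members that rose was left (jackknife SE 42.5), so RNA of B cells and plasma cells, or another factor that varies with it between mice, cannot be told apart from a difference between the populations, because 12 libraries give too wide an error. In the same fit the B cell genes themselves left 13.6% (SE 15.1).

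Il10 was also higher in TLCP and is made by some B lineage cells. The linear fit left 122% (SE 36.8) of the difference for Il10. This is above 50%, but not by more than 2 SE, so RNA of B cells and plasma cells cannot be told apart from a difference between the T cell populations here.

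Of 462 ways to split the 12 libraries into 6 and 6, 100 were drawn with the real one included. The real split called 3983 genes and the highest other 241, and 1170 genes with at least 2-fold change against 90, so in each case 1 of 100 splits was as large and chance can be excluded. The highest other split exchanged TLCP replicate 2 and Tfh replicate 4. Among the 32 splits that part all pairs, 1 was as large for both counts and the highest other count was 0. Chance cannot be excluded for the number of lists: 12 lists passed, but 15 of the 100 splits passed as many, with a highest other of 16, and 5 of the 32 splits that part all pairs passed as many, with a highest other of 13. Of the 14 other drawn splits that passed as many, 13 kept 4 or 5 libraries of 1 population on a side and so held part of the contrast. The 52 drawn splits with 3 of each population on both sides passed a median of 4 lists, and 1 of them passed 12. The 10 such splits among those that part all pairs passed a median of 1.5 and at most 6. The 12 lists ranked singly were those of 24 that passed in the real split. Their ranks thus follow a choice on the same p, were not corrected for it, and do not by themselves exclude chance. The number of the 100 splits with a camera p as small was 1 for germinal center Tfh, type 1 regulatory and trafficking genes and 3 for progenitor and memory genes, a share under 0.05 (real p 5.1e-27, 3.9e-09, 1.6e-06 and 0.00045, smallest other 1.4e-11, 3.0e-05, 0.00020 and 0.00014). It was 5 for Th1 and cytotoxic genes, 6 for regulatory T cell genes, 14 for dendritic cell, 15 for interferon-stimulated, 20 for plasma cell, 23 for B cell, 24 for oxidative phosphorylation and 39 for early response genes, for which these splits, many of which held part of the contrast, do not exclude chance. Among the 32 splits that part all pairs, 1 is the smallest number possible. With the same test without the block, the number was 1 for germinal center Tfh, progenitor and memory, type 1 regulatory and trafficking genes, and also 1 for Th1 and cytotoxic genes (real p 3.5e-12, smallest other 4.5e-11) and interferon-stimulated genes (0.00038 and 0.0016), a share under 0.05 that was likewise not corrected. It was 2 for early response, 3 for regulatory T cell, plasma cell and dendritic cell, 4 for B cell and 12 for oxidative phosphorylation genes, for which this rank does not exclude chance. Camera sets a list against all other genes, many of which also moved in the real split. For B cell genes its p was 1.7e-07 there and 7.0e-17 in a drawn split with 0 genes called. The rank therefore says little about the list genes themselves, and 14 of 16 B cell genes were called in the real split.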

How the results depend on the processing

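The recovered reads, leaving out ribosomal RNA genes, scaling by totals alone, upper quartile scaling, the sets of mice and leaving out the 2 TLCP libraries with the most immunoglobulin were chosen after seeing the data. The number of genes called stayed within 1.5 times of 3983 under every alternative run, and was 3489 to 4008 when a library was left out. The number with at least 2-fold change was then 1099 to 1250 and the number of lists 11 to 12. Similar counts did not always mean the same genes. Of the 3983 calls, 2906 were kept with totals alone and 2333 with limma on the TPM values. With the replicate block 4453 genes were called, 3930 of them shared, and the block changed no call of a named gene; of list calls with the preset correlation it changed the inhibitory list (0.02762) and the macrophage list. Direction depended on scaling: with totals alone 3207 genes were higher and 893 lower. These totals include CT010467.1, whose mean share was 17.3% in TLCP and 24.7% in Tfh. Limma on TPM gave 3176 higher and 465 lower (174 at least 2-fold). It also changed the test, the unit and the genes tested (13206), so its counts cannot be put down to scaling alone. With an estimated correlation 1 list passed, and with the replicate block and an estimated correlation 6. The adjusted p of lists that lost their call under these were 0.2767 and 0.1832 for progenitor and memory, 0.2703 (first only) for Th1 and cytotoxic, 0.07373 and 0.09206 for type 1 regulatory, 0.2767 and 0.4347 for regulatory, 0.07373 and 0.08405 for trafficking, 0.6242 and 0.1265 for early response, 0.3063 (first only) for interferon-stimulated and B cell, 0.3462 (first only) for plasma cell, 0.2767 (first only) for dendritic cell and 0.3462 and 0.4074 for oxidative phosphorylation. The 6 lists that passed under both together were germinal center Tfh (0.020) and Th1, interferon-stimulated, B cell, plasma cell and dendritic cell (0.02094 each). Early response genes were also at 0.1203 without the 2 immunoglobulin-rich TLCP libraries, and ranged from 0.008589 to 0.05782 when a library was left out. Lists that gained a call were inhibitory with no filter (0.03006), fry (0.008909) and mice 1 to 3 (0.003454), cytokines with fry (0.0004278) and mice 4 to 6 (0.04458), glycolysis with mice 4 to 6 (0.01602), ribosomal with mice 1 to 3 (0.02276), macrophage with no filter (0.0003002) and mice 4 to 6 (0.00765) and erythroid and platelet with mice 1 to 3 (0.02466), beside the 2 gained with the block. The cause was not tested, other than that fry compares no list with other genes and the sets of mice hold fewer libraries. Lists that changed direction without passing were Th2 and Th17 with DESeq2 (0.9695), totals alone (0.8353), mice 1 to 3 (0.8297) and without the 2 immunoglobulin-rich libraries (0.9031; 0.4348 to 0.9714 with a library left out), cell cycle with mice 1 to 3 (0.3572) and without those libraries (0.8322; 0.4954 to 0.9348 with a library left out), ribosomal with mice 4 to 6 (0.492), the list neutrophil with no filter (0.7089) and mice 4 to 6 (0.06613), and the list erythroid_platelet with mice 4 to 6 (0.4947). Calls shared with the authors' table numbered 1158 at 2-fold, where fewer genes qualify.

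No called named gene changed direction. Genes not called that did were Neil1 (0.0268), Icos (0.0801), Cd3e (0.12) and Cd8b1 (0.16) with totals alone; Icos (0.0108), Cd8b1 (0.15), Car1 (-0.0884) and Ighg2c (-0.0558) without the 2 immunoglobulin-rich libraries; Cd3e (0.0139) and Cd8b1 (0.0645) with mice 1 to 3; Car1 (-0.58), Hbb-bs (-0.40) and Lyz2 (-0.0759) with mice 4 to 6; and Cd8b1 with RLE (0.00021), DESeq2 (0.000902) and unstranded counts (0.0038). With a library left out Cd8b1 (-0.169 to 0.0686) and Car1 (-0.142 to 0.784) also changed sign, in 10 fits. Named genes that lost their call were Ccnb1 (-0.57, as reported -0.53), Gata3 (-0.41, -0.44), Nsdhl (0.51, 0.52), Rpl10a (0.57, 0.72), H2-Aa (1.95, 2.05) and Cd74 (2.05, 2.13) with mice 4 to 6, where the fold stayed about as large for all but Rpl10a and fewer libraries were tested, Ccnb1 (-0.36), Gata3 (-0.27) and Hk1 (-0.13, as reported -0.30) with totals alone, and Mki67 with mice 1 to 3 (0.10, adjusted p = 0.34) and without the 2 immunoglobulin-rich libraries (0.27, adjusted p = 0.054; as reported 0.39). Car1 (1.81) and Mpo (4.48) gained a call with mice 1 to 3. Without the 2 immunoglobulin-rich libraries 3129 genes were called.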

Other observations

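The genes in this part were picked after their values were seen. Besides Mcpt8 and Prss34, other transcripts of basophils and mast cells were higher in TLCP in all 6 pairs: Ms4a2, a chain of the IgE receptor, at 6.03 ± 1.97 CPM against 0.188 ± 0.200 CPM in Tfh (n = 6 each), Cpa3, a carboxypeptidase, at 10.3 ± 5.14 against 0.630 ± 0.979 CPM, and Gata2, a transcription factor, at 3.46 ± 1.11 against 0.531 ± 0.285 CPM. Hdc, the histamine-forming enzyme, had a log2 fold change of 1.51 (SE 0.49, edgeR adjusted p = 0.023). Among genes outside the lists, Art2a was 4.18 ± 1.09 CPM in TLCP and 80.2 ± 8.86 CPM in Tfh, and Padi4, an arginine deiminase gene, was 2.95 ± 0.848 against 49.5 ± 10.3 CPM. Hif1a, the oxygen-sensing transcription factor, fell from 1405 ± 139 to 563 ± 58.9 CPM and Cd44, an adhesion receptor, from 405 ± 37.8 to 176 ± 25.3 CPM. Adam19 rose from 102 ± 11.6 to 279 ± 25.2 CPM, Gbp4 from 169 ± 11.7 to 393 ± 59.0 CPM, Gbp8 from 41.0 ± 4.45 to 101 ± 10.5 CPM, Pim1 from 86.5 ± 9.54 to 186 ± 23.0 CPM and Socs3 from 34.6 ± 7.48 to 84.1 ± 7.84 CPM.

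Hspa1a, a heat shock gene with a near-identical copy in Hspa1b, was 3.78, 9.72 and 4.43 CPM in TLCP replicates 4, 5 and 6 and 4.14, 9.79 and 3.83 CPM in Tfh replicates 4, 5 and 6. In the 6 libraries of mice 1 to 3 its highest value was 0.359 CPM. No label gives a reason, and no test between these sets of mice is reported, since the sets were seen in the data and are not given by the study. Between the populations Hspa1a had a log2 fold change of 0.05 (SE 1.3). Between the populations 3336 genes were called in mice 1 to 3 and 2792 in mice 4 to 6, of which 1902 were called in both and 3 of these had opposite signs.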
